A study of Mus musculus with 6 samples.

How the data were processed

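Single-cell RNA sequencing was carried out on differentiated monolayers grown from mouse intestinal organoids. The labels give 3 groups of 2 libraries, named by the series text as biological replicates: DMSO, tunicamycin at 0.5 µg/ml for 13 h, and tunicamycin at the same dose for 25 h. Tunicamycin blocks the first step of N-linked glycosylation, catalysed by the product of Dpagt1, and so causes stress of the endoplasmic reticulum (ER). Per the labels, treatment started on differentiation day 3, the 13 h set stood in DMSO before tunicamycin was added, and all sets were harvested on the morning of day 4. Monolayers were scraped and dissociated, dead cells were removed with a kit, and libraries were made with the 10x Genomics 3' V2 chemistry, per the extract protocol. The growth protocol names colonic spheroids while the tissue tag names small intestine, and the sources used here do not settle which applies.

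The authors deposited a single matrix of raw counts, each a number of unique molecular identifiers (UMIs) for a gene in a cell, with 27998 genes and 5122 cells. Per the submitters' processing notes, reads were processed with Cell Ranger against mm10. The Cell Ranger version, the filter that chose the deposited cells and the number of cells loaded per library are not given in the sources used here. Each deposited cell name holds its library, its barcode and the authors' class (enterocyte, goblet or tuft), so cells were assigned to samples and classes by name. How the authors assigned the classes is not given in the sources used here. Of the barcode sequences, 12 occurred in more than a single library and were kept apart by library. The rows carry Ensembl identifiers without symbols. Symbols and coordinates came from GENCODE vM21 on GRCm38, the same assembly as mm10, which matched 27645 of the 27998 identifiers.

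Deposited cells and their total UMIs were 1205 and 19772274 for DMSO replicate 1, 1187 and 18647575 for DMSO replicate 2, 801 and 13958820 for 13 h replicate 1, and 837 and 14799752 for 13 h replicate 2. They were 541 and 9462248 for 25 h replicate 1, and 551 and 10436579 for 25 h replicate 2. Median UMIs per deposited cell were between 14395 and 17244, and single cells held between 3090 and 157040. Cells with at least 1000 UMIs, at least 500 genes and at most 25% mitochondrial UMIs were kept. This removed 96 cells, all for mitochondrial UMIs, and left 5026. Scrublet in scanpy 1.11.5 called 31 of the deposited cells doublets (0.605%).

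Counts were summed per sample over all cells, and per sample within each class. All 6 samples entered a single fit per class with group as the only term. Genes were filtered with filterByExpr, libraries were scaled by the trimmed mean of M-values (TMM), and groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. This tested 11474 genes in all cells, 11145 in enterocytes and 7839 in goblet cells. The biological coefficient of variation was 0.0493 in all cells, 0.0418 in enterocytes and 0.0788 in goblet cells. The p-values of gene tests measure the spread between these samples. That of the enterocyte share at 25 h against DMSO did not change without either 13 h library, so it follows cell counts rather than that spread. Errors of fold changes are standard errors of the fit (SE). Expression levels are given in CPM from TMM-scaled libraries, and their errors are standard deviations over 2 libraries (SD). Differences between classes in their response were tested as the interaction of class and group, with each sample as a block, over 10458 genes. Class shares were tested with the same edgeR test on cell counts, and intervals of single shares are 95% exact binomial (Clopper-Pearson), which cover counting error only. The class named tuft had between 12 and 27 cells per sample, in some samples below the minimum of 20 set for a fit. Its fit was added after the data were seen.

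In all, 38 gene lists were fixed: 22 of pathways, 4 by name pattern and 12 of cell type markers, of which 35 had enough measured members. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. For each list the members that changed were counted with p-values adjusted over all genes and adjusted over the list alone. Genes named per comparison were the 10 highest and 10 lowest fold changes among genes past the threshold with a mean of at least 20 CPM and both libraries of a group beyond both of the other. Up to 4 members per list with the lowest adjusted p were added, and Hspa5, Ddit3, Atf4, Xbp1, Dpagt1 and Qrich1 were always included, which gave 248 genes in total. Genes outside this rule are named as such. Some genes that the rule selects are not reported. The groups, main tests, lists, naming rule and most alternatives were chosen before the data were examined. For the spread between cells, each cell was thinned to 5000 UMIs, and cells with fewer were left out.

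The procedure was tested on simulated data with the depths and spread of the 13 h comparison and 100 changed genes of each size. In all cells it recovered 62% of changes of 0.5 and 90% of changes of 1 on the log2 scale, with 8 false calls. In enterocytes the figures were 70% and 86% with 3 false calls, and in goblet cells 14% and 70% with 8. The simulated list that moved was called, and 0 of the lists that did not move were. Genes were simulated independently of each other. The run thus does not show how the list test behaves where genes of a list vary together.

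Alternatives were DESeq2 1.42.0, edgeR without TMM, no low-count filter, no cell filter, a stricter cell filter (at least 2000 UMIs and at most 10% mitochondrial UMIs), 537 cells drawn from every sample, removal of called doublets, a replicate term and the omission of each sample in turn. Between samples of the same replicate number the correlations of residuals across 5108 genes were 0.153, -0.245 and -0.177, so the numbers were not taken as pairs. Clustering was planned in case the files held no cell types. The authors' classes were used in its place, so the planned resolutions, component numbers and pooled fallback were not run. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.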

Results

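The series title asks which time-dependent transcriptional programs decide the outcome of ER stress. To that end 6 single-cell RNA libraries were made from differentiated monolayers of mouse intestinal organoids, with 2 libraries for each of DMSO, 13 h of tunicamycin and 25 h of tunicamycin. Tunicamycin inhibits N-linked glycosylation, so that unfolded glycoproteins accumulate in the ER. After the filter on mitochondrial UMIs, 1178 and 1165 cells remained from DMSO, 780 and 821 from 13 h, and 537 and 545 from 25 h. Total UMIs per deposited library ranged from 9462248 to 19772274, and the median cell held between 14395 and 17244 UMIs. The share of UMIs from the mitochondrial genome was 9.23% in both DMSO libraries, 8.76% and 9.08% at 13 h, and 7.60% and 7.39% at 25 h. Fold changes are from edgeR on summed counts, and a gene or list is said to rise or fall only where its Benjamini-Hochberg adjusted p was below 0.05.

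Goblet cells, the mucus-secreting cells of the epithelium, made up 9.13 ± 0.313% of cells in DMSO (SD, n = 2), 9.50 ± 0.521% at 13 h and 17.0 ± 1.75% at 25 h. Their share was higher at 25 h than in DMSO (log2 ratio 0.90, edgeR, adjusted p = 3.33e-05) and than at 13 h (0.84, adjusted p = 4.95e-05), in both 25 h libraries. Per library it was 8.91% and 9.36% in DMSO, 9.87% and 9.14% at 13 h, and 18.2% (95% exact interval 15.1 to 21.8) and 15.8% (12.8 to 19.1) at 25 h. Enterocytes, the absorptive cells, made up 88.9 ± 0.154%, 88.2 ± 0.339% and 80.7 ± 1.90%. Per library they made up 88.8% (86.9 to 90.5) and 89.0% (87.1 to 90.8) in DMSO, and 79.3% (75.7 to 82.7) and 82.0% (78.5 to 85.2) at 25 h. These DMSO and 25 h intervals did not overlap. Shares of a sample are complementary, so this fall and the goblet rise are not separate results. By the edgeR test, which here follows cell counts rather than the spread between libraries, the lower share of enterocytes at 25 h passed against DMSO (log2 ratio -0.14, adjusted p = 0.0463). It did not pass with the stricter cell filter (-0.15, adjusted p = 0.110). Nor did it pass without either DMSO library (adjusted p = 0.0856 each), without 25 h replicate 1 (0.356) or without 25 h replicate 2 (0.0901). The goblet rise passed with the stricter cell filter at smaller log2 ratios (0.70 against DMSO and 0.70 against 13 h, edgeR, adjusted p = 4.6e-04 each). In DMSO replicate 1 that filter left 619 of 1046 enterocytes and 95 of 105 goblet cells. The class named tuft, after rare chemosensory cells, made up 1.96 ± 0.467%, 2.31 ± 0.181% and 2.31 ± 0.155%, with no difference that passed (25 h against DMSO 0.23, adjusted p = 0.774). At equal depth at least 3 tuft markers were detected in 2 of its 45 DMSO cells and 10 of its 36 cells at 13 h, and at least 3 enteroendocrine markers in 9 and 2, while among 2057 enterocytes in DMSO each was met by 1. The numbers of goblet cells counted were 105 and 109 in DMSO, 77 and 75 at 13 h, and 98 and 86 at 25 h.

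**Figure D1:**
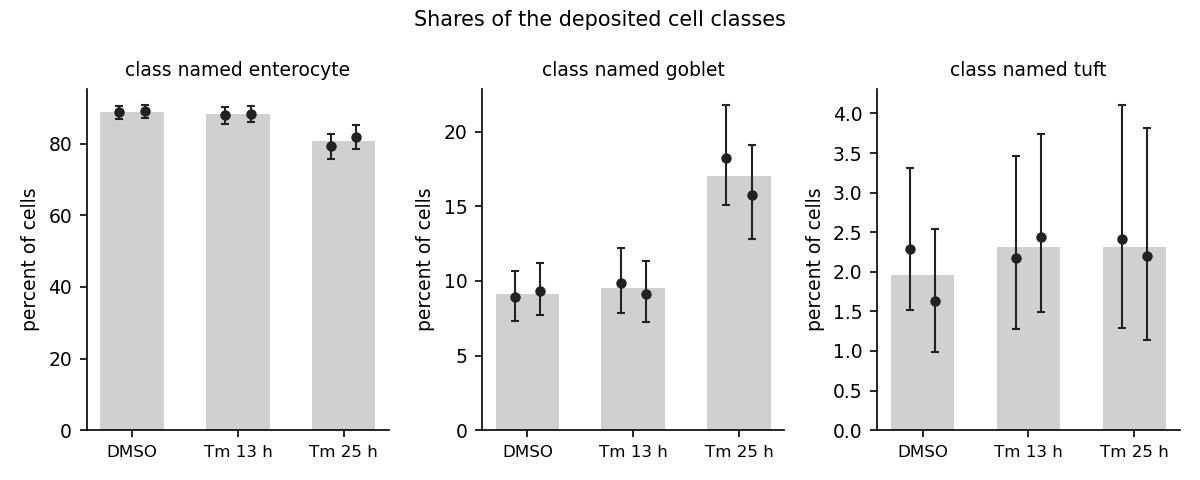
Percent of cells in each of the authors' classes. Bars are means of 2 libraries, points are single libraries with 95% exact binomial intervals. The goblet bar stands at 17.0% at 25 h against 9.13% in DMSO.

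The comparison of 13 h of tunicamycin with DMSO shows the earlier response. ER chaperones and their partners rose strongly. In both tunicamycin libraries Hspa5, which encodes the main Hsp70 chaperone of the ER lumen, rose 22.3-fold (log2 fold change 4.48 ± 0.09 SE, n = 2 libraries per group, adjusted p = 1.4e-11), from 220 ± 34.8 to 4914 ± 113 CPM. The disulfide isomerase gene Pdia6 rose 15.5-fold (3.96 ± 0.06), and Ddit3, which encodes the stress transcription factor CHOP, rose 16.9-fold (4.08 ± 0.11). Derl3, a component of the channel that returns misfolded proteins to the cytosol, had 0.465 CPM in DMSO and 60.0 CPM at 13 h (6.99 ± 0.15). Ifit1, an interferon-induced gene (-1.99 ± 0.05), and Fabp2, which encodes a fatty acid-binding protein (-1.65 ± 0.05), fell.

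Of 21 measured ER chaperone and folding genes, 20 rose and 0 fell (also 20 and 0 adjusted over the list alone), with a median log2 fold change of 2.14 (camera, adjusted p = 4.2e-17; adjusted p = 0.162 with an estimated correlation). They included Creld2 (4.14), Sdf2l1 (3.72), Hyou1 (3.64), Pdia4 (3.55), Hsp90b1 (3.48) and Manf (3.47). Of 19 genes of ER-associated degradation 16 rose and 0 fell (17 and 0 adjusted over the list alone), with Syvn1 (2.54), Selenos (2.07) and Sel1l (1.94) beside Derl3. Of 27 genes of ER translocation and vesicle transport 25 rose and 0 fell (25 and 0 adjusted over the list alone), among them the translocon subunit Sec61a1 (1.58) and the signal peptidase subunit Spcs2 (1.48). Of 22 genes of N-glycosylation 17 rose and 1 fell (18 and 1 adjusted over the list alone), with Ostc (1.85) and Rpn1 (1.54), both parts of the oligosaccharyltransferase. Dpagt1, whose product is the target of tunicamycin, rose 2.18-fold (1.12 ± 0.08). The 3 lists had camera adjusted p = 5.25e-09, 2.6e-13 and 6.68e-09 (adjusted p = 0.180, 0.180 and 0.162 with an estimated correlation).

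Of 14 sensors and regulators of the unfolded protein response 8 rose and 0 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.00646; adjusted p = 0.162 with an estimated correlation). Xbp1, the transcription factor that is spliced by IRE1, rose 3.55-fold (1.83 ± 0.05), and Atf6 (0.85) and Creb3l2 (1.59) also rose. All 17 measured regulators of the PERK-ATF4 branch rose (17 and 0 adjusted over the list alone), with a median of 1.99 (camera, adjusted p = 2.38e-11; adjusted p = 0.162 with an estimated correlation). Atf4 rose 3.51-fold (1.81 ± 0.05), the pseudokinase gene Trib3 rose 10.2-fold (3.35 ± 0.10), and Atf5 (3.41) and Atf3 (2.32) rose as well. Qrich1, a transcriptional regulator, rose by less (0.38 ± 0.07, adjusted p = 0.001). Of 19 genes of amino acid synthesis and transport 18 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 2.22. They included the mitochondrial folate enzyme gene Mthfd2 (2.50), the cystine transporter gene Slc7a11 (2.40) with its partner Slc3a2 (2.29), and asparagine synthetase Asns (2.18). Of 20 aminoacyl-tRNA synthetase genes 19 rose and 0 fell (19 and 0 adjusted over the list alone), such as Wars (2.03) and Eprs (1.84). Of 20 translation factors 15 rose and 0 fell (16 and 0 adjusted over the list alone), led by Eif4ebp1 (1.82), which encodes an inhibitor of cap-dependent translation. These lists had camera adjusted p = 1.47e-11, 2.38e-11 and 1.75e-06, and adjusted p = 0.162 with an estimated correlation in each case.

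Of 18 interferon-response genes 0 rose and 16 fell (0 and 16 adjusted over the list alone), with a median of -1.13 (camera, adjusted p = 2.53e-07; adjusted p = 0.162 with an estimated correlation), among them Ifit3 (-2.30), Ifit1 (-1.99), Oasl2 (-1.73) and Isg15 (-1.21). Of 20 genes of cholesterol synthesis 0 rose and 19 fell (0 and 19 adjusted over the list alone, median -0.53; camera, adjusted p = 3.96e-08; adjusted p = 0.272 with an estimated correlation), with Acat2 (-1.40), Dhcr7 (-1.37) and Idi1 (-1.07). Of 18 markers of enterocytes 0 rose and 16 fell (0 and 16 adjusted over the list alone, median -0.72; camera, adjusted p = 5.68e-07; adjusted p = 0.162 with an estimated correlation). Fabp2 was among them, with the apolipoprotein genes Apoa4 (-1.43) and Apoc3 (-1.38). Of 18 NRF2 targets 1 rose and 15 fell (1 and 15 adjusted over the list alone, camera adjusted p = 1.04e-04; adjusted p = 0.162 with an estimated correlation). The glutathione synthesis gene Gclm was at -0.77, whereas Hmox1, which encodes heme oxygenase 1, rose 4.08-fold. Of 14 antigen presentation genes 0 rose and 6 fell (0 and 6 adjusted over the list alone, camera adjusted p = 0.00374; adjusted p = 0.162 with an estimated correlation), with Psmb9 (-1.13) and B2m (-0.60). Among the largest falls outside the lists were Ifit1bl1 (-2.49), Apol7a (-1.91), Adh6a (-1.85), Apol10a (-1.76) and Fa2h (-1.66). Reads of Ifit1bl1, Apol7a and Apol10a are assigned among closely related family members, and that assignment was not analysed here.

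Ribosomal protein genes rose in 66 of 92 cases and fell in 3 (68 and 3 adjusted over the list alone), with a median of 0.30 (camera, adjusted p = 1.15e-10; adjusted p = 0.404 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 62 of 79 cases and rose in 6 (65 and 6 adjusted over the list alone), with a median of -0.30 (camera, adjusted p = 1.65e-08; adjusted p = 0.404 with an estimated correlation). Of 13 genes of the mitochondrial genome 6 fell, or 2 when libraries were scaled by total counts, and the list was not called (camera, adjusted p = 0.0966). Of 31 histone genes, many of which share sequence, 16 rose and 3 fell (17 and 4 adjusted over the list alone, camera adjusted p = 0.0168; adjusted p = 0.250 with an estimated correlation). Of 13 goblet markers 1 rose and 7 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.0148; adjusted p = 0.180 with an estimated correlation), with the mucin gene Muc2 at -1.14 and the trefoil factor gene Tff3 at -0.59, while Agr2, a disulfide isomerase needed for mucin folding, rose (0.83). All 9 tuft markers rose (9 and 0 adjusted over the list alone, median 2.73; camera, adjusted p = 0.0139; adjusted p = 0.436 with an estimated correlation), or 4 with DESeq2, and the list was not called by fry (adjusted p = 0.0939) or without 13 h replicate 2 (camera, adjusted p = 0.0531). The median was 1.52 without that library, 2.17 without DMSO replicate 2 and 3.27 without 13 h replicate 1.

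In the cells left after removal of dead cells, genes of cell death and of p53 moved in both directions at 13 h, and neither list was called. Of 23 apoptosis regulators 4 rose and 9 fell (5 and 9 adjusted over the list alone, camera adjusted p = 0.255), with the BH3-only genes Bcl2l11 (-0.91) and Bmf (-0.93) lower. Of 14 p53 targets 3 rose and 4 fell (3 and 4 adjusted over the list alone, median -0.06, mean 0.08, with a positive median under total-count scaling and the stricter cell filter; adjusted p = 0.919). Trp53inp1 rose (1.35) and Cdkn1a, the cell cycle inhibitor p21, fell (-0.26). The chemokine gene Ccl20 rose 4.52-fold and the growth factor genes Areg and Ereg, ligands of the EGF receptor, rose 7.51-fold and 6.57-fold. Of 12 NF-kB and chemokine genes 2 rose and 4 fell, of 11 regenerative epithelium markers 3 rose and 1 fell, of 4 enteroendocrine markers 0 rose and 3 fell, and of 7 known substrates of IRE1-dependent decay 4 rose and 1 fell (2 and 4, 3 and 1, 0 and 3, and 4 and 1 adjusted over the list alone). The NF-kB list had a median just below 0 and a mean of 0.06. None of these 4 lists was called (adjusted p = 0.968, 0.201, 0.0717 and 0.260). The list of decay substrates shares Rpn1, which rose, with the N-glycosylation list, and RNA decay itself was not measured. In total 2454 genes rose and 2787 fell of 11474 tested, of which 464 and 384 changed by at least 2-fold. With DESeq2 1855 genes fell, and with scaling by total counts 3120 rose and 2180 fell, which took the share of higher genes among those called from 46.8% to 58.9%.

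**Figure D2:**
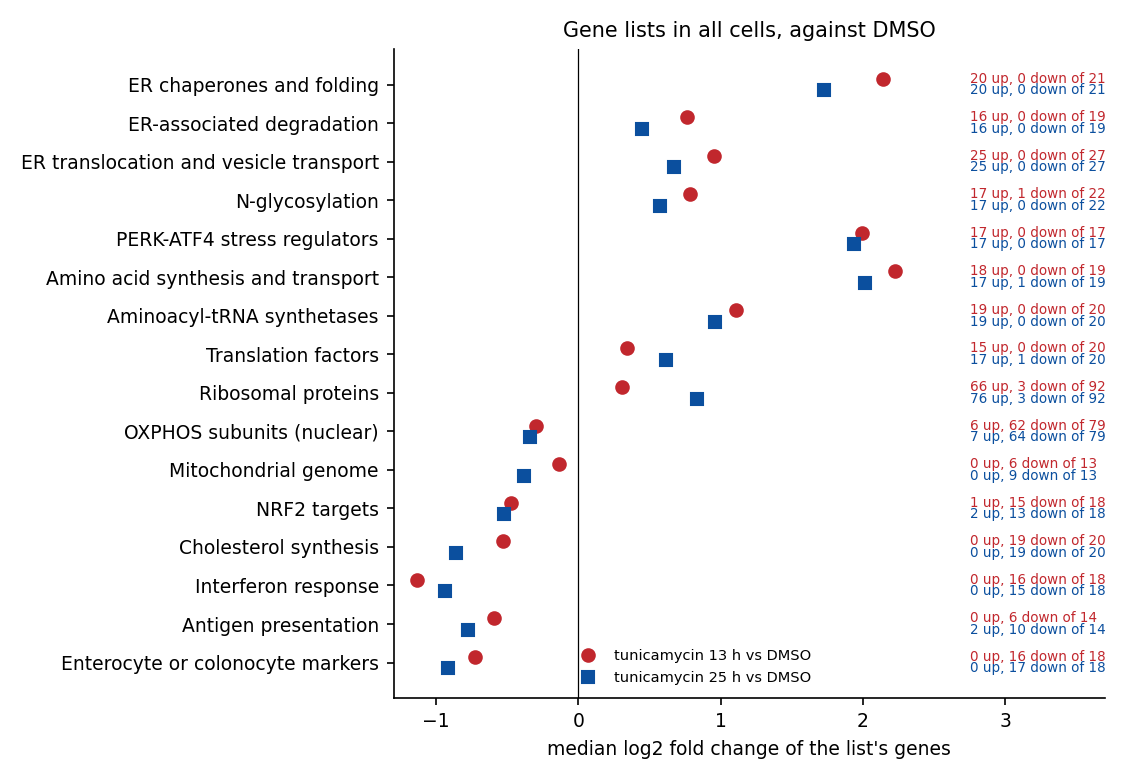
Median log2 fold change against DMSO of the measured members of 16 gene lists, at 13 h (circles) and 25 h (squares), with the numbers of genes that rose and fell at the right. ER chaperones stand at 2.14 and 1.73, and ribosomal proteins at 0.30 and 0.83.

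The comparison of 25 h of tunicamycin with DMSO shows the later state. ER stress genes were still far above DMSO: Hspa5 was 13.7-fold higher (3.78 ± 0.09 SE, n = 2 per group, adjusted p = 5.4e-11) at 3026 ± 144 CPM, Pdia6 11.7-fold (3.55 ± 0.05) and Ddit3 9.89-fold (3.31 ± 0.11). Atf5, a transcription factor of the ATF4 branch, rose 14.4-fold (3.85 ± 0.07). Rps6, a protein of the small ribosomal subunit, rose (1.40), and Apoa4, which encodes an apolipoprotein, fell (-2.59 ± 0.12). The metallothionein genes Mt2 (-3.76 ± 0.14) and Mt1 (-2.86 ± 0.09), which encode metal-binding proteins, and Saa1, which encodes an acute-phase protein (-3.29 ± 0.07), were among the genes that fell most.

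All 17 PERK-ATF4 regulators rose (17 and 0 adjusted over the list alone, median 1.94), with Trib3 at 9.54-fold, Atf4 at 3.25-fold and Atf3 at 2.02 on the log2 scale. Of 21 ER chaperone genes 20 rose and 0 fell (20 and 0 adjusted over the list alone, median 1.73), including Sdf2l1 (3.23), Manf (3.06) and calreticulin, Calr (2.70). The numbers that rose and fell were 16 and 0 of 19 for ER-associated degradation, 25 and 0 of 27 for translocation and 17 and 0 of 22 for N-glycosylation (16 and 0, 25 and 0, and 18 and 1 adjusted over the list alone). Derl3 was at 5.68 ± 0.19, Dpagt1 at 0.73 ± 0.09 and Xbp1 at 1.68 ± 0.05. Camera gave adjusted p = 2.58e-09, 1.08e-13, 7.68e-07, 9.14e-10 and 6.81e-07 for the 5 lists in this order (adjusted p = 0.201, 0.201, 0.221, 0.221 and 0.201 with an estimated correlation). Among sensors and regulators 9 rose and 1 fell of 14 (9 and 1 adjusted over the list alone, camera adjusted p = 0.00735; adjusted p = 0.205 with an estimated correlation). Qrich1 was at 0.29 ± 0.08 (adjusted p = 0.0076), which did not pass without 25 h replicate 1 (adjusted p = 0.0830).

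Genes that supply protein synthesis rose at 25 h. Of 92 ribosomal protein genes 76 rose and 3 fell (77 and 3 adjusted over the list alone, median 0.83; camera, adjusted p = 2.15e-16; adjusted p = 0.320 with an estimated correlation), with Rps6 (1.40), Rpl14 (1.27) and Rpl10 (1.27). Of 20 translation factors 17 rose and 1 fell (17 and 1 adjusted over the list alone, camera adjusted p = 7.68e-07; adjusted p = 0.169 with an estimated correlation), among them the elongation factor genes Eef1g (1.42) and Eef1a1 (1.07). Aminoacyl-tRNA synthetases rose in 19 of 20 cases with 0 lower (19 and 0 adjusted over the list alone, camera adjusted p = 6.26e-10; adjusted p = 0.169 with an estimated correlation), with Iars at 2.17. Of 19 genes of amino acid synthesis and transport 17 rose and 1 fell (17 and 1 adjusted over the list alone, camera adjusted p = 9.53e-09; adjusted p = 0.169 with an estimated correlation), with Asns at 2.01. The lipid droplet enzyme gene Hsd17b13 rose 13.1-fold, and Ppm1j and Adm2, which encodes a peptide hormone of the calcitonin family, 10.2-fold each.

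Absorptive genes were lower. Of 18 enterocyte markers 0 rose and 17 fell (0 and 18 adjusted over the list alone, median -0.92; camera, adjusted p = 2.81e-08; adjusted p = 0.201 with an estimated correlation), including Apoa4 (-2.59), Apoc3 (-2.58), Fabp2 (-2.12), the brush border phosphatase Alpi (-1.98) and Ceacam1 (-1.89). The phosphate transporter gene Slc34a2 (-2.64), the calcium-binding protein gene S100g (-2.61) and the trypsin inhibitor gene Spink1 (-2.87) fell as well. Of 8 genes typical of small intestine 1 rose and 5 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.0111; adjusted p = 0.205 with an estimated correlation), and of 5 genes typical of colon 2 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.599). Both lists share genes with the enterocyte markers, such as Apoa4 and Fabp2 for small intestine and Car1 for colon. They are therefore not results separate from the enterocyte markers. The lower share of enterocytes at 25 h stands beside these falls, which were also seen within enterocytes. Of 20 cholesterol genes 0 rose and 19 fell (0 and 19 adjusted over the list alone, median -0.86; camera, adjusted p = 1.86e-09; adjusted p = 0.221 with an estimated correlation), with Idi1 (-1.47) and Hmgcs1 (-1.33). Of 18 interferon-response genes 0 rose and 15 fell (0 and 16 adjusted over the list alone, camera adjusted p = 1.11e-05; adjusted p = 0.205 with an estimated correlation), with Ifit1 (-2.18), Oasl2 (-1.86) and Isg15 (-1.36). Of 14 antigen presentation genes 2 rose and 10 fell (2 and 10 adjusted over the list alone, camera adjusted p = 0.00513; adjusted p = 0.205 with an estimated correlation), with B2m (-1.08) and H2-Q1 (-1.03). Of 18 NRF2 targets 2 rose and 13 fell (2 and 14 adjusted over the list alone, camera adjusted p = 0.00144; adjusted p = 0.220 with an estimated correlation).

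Nuclear genes of oxidative phosphorylation fell in 64 of 79 cases and rose in 7 (65 and 7 adjusted over the list alone, camera adjusted p = 3.4e-08; adjusted p = 0.399 with an estimated correlation), with the muscle-type subunit gene Cox7a1 at -1.88. Another muscle-type subunit gene, Cox6a2, rose from a level below 1 CPM (4.36 ± 0.34 at 13 h and 4.79 ± 0.33 at 25 h). Of 13 mitochondrially encoded genes 0 rose and 9 fell (0 and 9 adjusted over the list alone, camera adjusted p = 0.00353; adjusted p = 0.279 with an estimated correlation), with mt-Co1 at -0.48. Of 23 apoptosis regulators 3 rose and 12 fell (3 and 12 adjusted over the list alone, median -0.29; camera, adjusted p = 0.047; adjusted p = 0.221 with an estimated correlation). That list holds genes for and against cell death: the pro-death gene Bax rose (0.50), the caspase gene Casp8 fell (-0.71) and the pro-survival gene Mcl1 fell (-0.59). Its call was lost without DMSO replicate 1 (adjusted p = 0.185) and without 25 h replicate 1 (adjusted p = 0.0598). Of 14 p53 targets 4 rose and 4 fell (4 and 4 adjusted over the list alone, median -0.04, or 0.03 with total-count scaling, mean 0.15, adjusted p = 0.753). Of 13 goblet markers 5 rose and 6 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.904; fry called them higher, adjusted p = 0.00506, while the median was -0.09), with Agr2 at 2.05 and the lectin gene Zg16 at -1.64. Of 9 tuft markers 3 rose (1 adjusted over the list alone), and the list was not called (adjusted p = 0.230). In total 2808 genes rose and 2991 fell, 578 and 544 of them by at least 2-fold. With scaling by total counts 3330 rose and 2489 fell, which took the share of higher genes among those called from 48.4% to 57.2%.

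The comparison of 25 h with 13 h shows what changed between the time points. Hspa5 was at -0.70 ± 0.08 (SE, n = 2 per group, adjusted p = 0.00012), Ddit3 at -0.78 ± 0.10 (adjusted p = 0.00024) and Derl3 at -1.31 ± 0.08. Rps6 rose (0.82 ± 0.04). Mt2 (-3.28 ± 0.14), Slc34a2 (-2.51 ± 0.11), S100g (-2.16 ± 0.07), Saa1 (-2.10 ± 0.07) and Mt1 (-1.92 ± 0.09) were among the genes that fell most.

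Of 21 chaperone genes 0 rose and 17 fell (0 and 18 adjusted over the list alone, median -0.39; camera, adjusted p = 2.83e-08), with Hyou1 (-0.79) and Pdia4 (-0.68). Of 19 genes of ER-associated degradation 0 rose and 8 fell (1 and 12 adjusted over the list alone, camera adjusted p = 9.33e-04), with Syvn1 (-1.08) and Herpud1 (-0.69). Of 27 translocation genes 2 rose and 13 fell, and of 22 N-glycosylation genes 2 rose and 11 fell (2 and 18, and 3 and 11 adjusted over the list alone, camera adjusted p = 3.74e-04 and 0.0299). The N-glycosylation call was lost without 13 h replicate 2 (adjusted p = 0.0851) and without 25 h replicate 2 (0.0893). Of 19 genes of amino acid synthesis and transport 1 rose and 8 fell (1 and 12 adjusted over the list alone, camera adjusted p = 0.00219), and of 20 cholesterol genes 1 rose and 16 fell (1 and 17 adjusted over the list alone, camera adjusted p = 4.57e-06). Of 92 ribosomal protein genes 65 rose and 1 fell (73 and 2 adjusted over the list alone, median 0.49; camera, adjusted p = 2.76e-21), among them Rpl4 (0.79) and Rpl5 (0.75). Translation factors rose in 5 and fell in 2 of 20 cases (6 and 2 adjusted over the list alone, camera adjusted p = 0.0396), with Eef1g at 0.80 and Eef1a1 at 0.74. That call was lost without DMSO replicate 1 (adjusted p = 0.0687), DMSO replicate 2 (0.0698), 13 h replicate 1 (0.0562), 13 h replicate 2 (0.100) or 25 h replicate 2 (0.125). Adjusted p = 0.472 for translocation, and 0.439 for the 7 other lists, with an estimated correlation.

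Of 17 PERK-ATF4 regulators 1 rose and 3 fell (1 and 3 adjusted over the list alone; adjusted p = 0.228). Atf5 rose (0.44), Atf4 was at -0.11 ± 0.05 (adjusted p = 0.16) and Qrich1 at -0.09 ± 0.07 (adjusted p = 0.44). Chac1, which encodes a glutathione-degrading enzyme, fell (-0.52). Dpagt1 fell (-0.39 ± 0.09, adjusted p = 0.0074), a call lost without 25 h replicate 1 (adjusted p = 0.0541). Xbp1 was at -0.15 ± 0.05 (adjusted p = 0.046), which did not pass without any of the 6 libraries in turn (adjusted p from 0.0509 to 0.158) or with DESeq2 (0.0887). Aminoacyl-tRNA synthetases were not called as a list (2 rose and 8 fell of 20, the same adjusted over the list alone; adjusted p = 0.0913). The cell cycle inhibitor gene Cdkn1a rose (0.35). Of 13 goblet markers 6 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.00185), with Muc2 (1.37), Agr2 (1.23), the transcription factor gene Atoh1 (0.76) and Tff3 (0.50), beside the larger share of goblet cells. Of 18 enterocyte markers 1 rose and 11 fell (2 and 12 adjusted over the list alone, camera adjusted p = 1.33e-04), of 8 small-intestinal genes 1 rose and 4 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.0178), and of 13 mitochondrially encoded genes 0 rose and 6 fell, or 3 with the stricter cell filter (0 and 7 adjusted over the list alone, camera adjusted p = 0.00456). Adjusted p = 0.439 in these 4 cases with an estimated correlation. The small-intestinal list shares genes with the enterocyte markers.

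In total 1027 genes rose and 1101 fell between 13 h and 25 h, 59 and 83 of them by at least 2-fold. These numbers were lower with DESeq2 (515 and 696). Without 13 h replicate 1 they were 553 and 645, and without 13 h replicate 2 the number that rose was 525. Of the 2454 genes that had risen at 13 h, 318 rose further, 358 fell and 1778 did not pass. Of the 2787 that had fallen at 13 h, 413 fell further, 311 rose and 2063 did not pass. A further 398 genes rose and 330 fell that had not passed at 13 h. The 13 h libraries enter the 13 h calls and the later change with opposite sign. Error in them favours falls among genes that had risen, and rises among genes that had fallen. Both comparisons with DMSO called 1925 genes higher and 2185 lower, and 50 in opposite directions. The last number was 26 without DMSO replicate 1, 24 without DMSO replicate 2, 27 without 13 h replicate 1 and 18 with DESeq2. They share the DMSO libraries, which makes calls overlap. Chance overlap of independent calls would give 601 and 727, and simulated libraries without an effect, sharing their controls, gave means of 0.55 and 0.45 over 20 simulations. These called few genes at all, with means of 1.9 higher and 2.1 lower at 13 h, so they set no scale for the overlap. The fold changes of both comparisons correlated across genes (r = 0.824, against 0.411 in the simulations), and genes are not independent replicates. With a separate DMSO library for each comparison, a split chosen after seeing the data, 1437 genes were called higher in both and 1725 lower with replicate 1 for 13 h and replicate 2 for 25 h. The reverse split gave 1422 and 1729. Independent calls would give 398 and 507 in the first split and 404 and 511 in the second. A lone DMSO library is assumed here to vary like the tunicamycin groups.

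Within the authors' classes the stress genes rose in enterocytes and in goblet cells. Hspa5 rose by 4.76 ± 0.11 on the log2 scale (SE) at 13 h in enterocytes and by 3.06 ± 0.10 in goblet cells. In enterocytes it went from 187 CPM in DMSO to 5056 at 13 h and 3036 at 25 h (n = 2 each), and in goblet cells from 544 to 4545 and 2984. Pdia6 went from 27.0 to 686 and 488 CPM in enterocytes and from 231 to 804 and 731 in goblet cells. Ddit3 went from 76.4 to 1317 and 772 CPM in enterocytes and from 48.4 to 859 and 556 in goblet cells. In enterocytes 2652 genes rose and 2655 fell of 11145 at 13 h, and 2905 and 2696 at 25 h. In goblet cells 849 rose and 905 fell of 7839 at 13 h, and 1235 and 1256 at 25 h. Without DMSO replicate 1 the goblet numbers were 500 and 533 at 13 h and 802 higher at 25 h, and without 13 h replicate 1 they were 559 and 566 at 13 h. From 13 h to 25 h, 1163 genes rose and 1217 fell in enterocytes, and 159 and 115 in goblet cells. For enterocytes 766 rose without 13 h replicate 1 and 773 without 13 h replicate 2. For goblet cells 90 rose and 49 fell without 13 h replicate 2, 73 fell without DMSO replicate 1 and 69 fell without 25 h replicate 2.

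**Figure D3:**
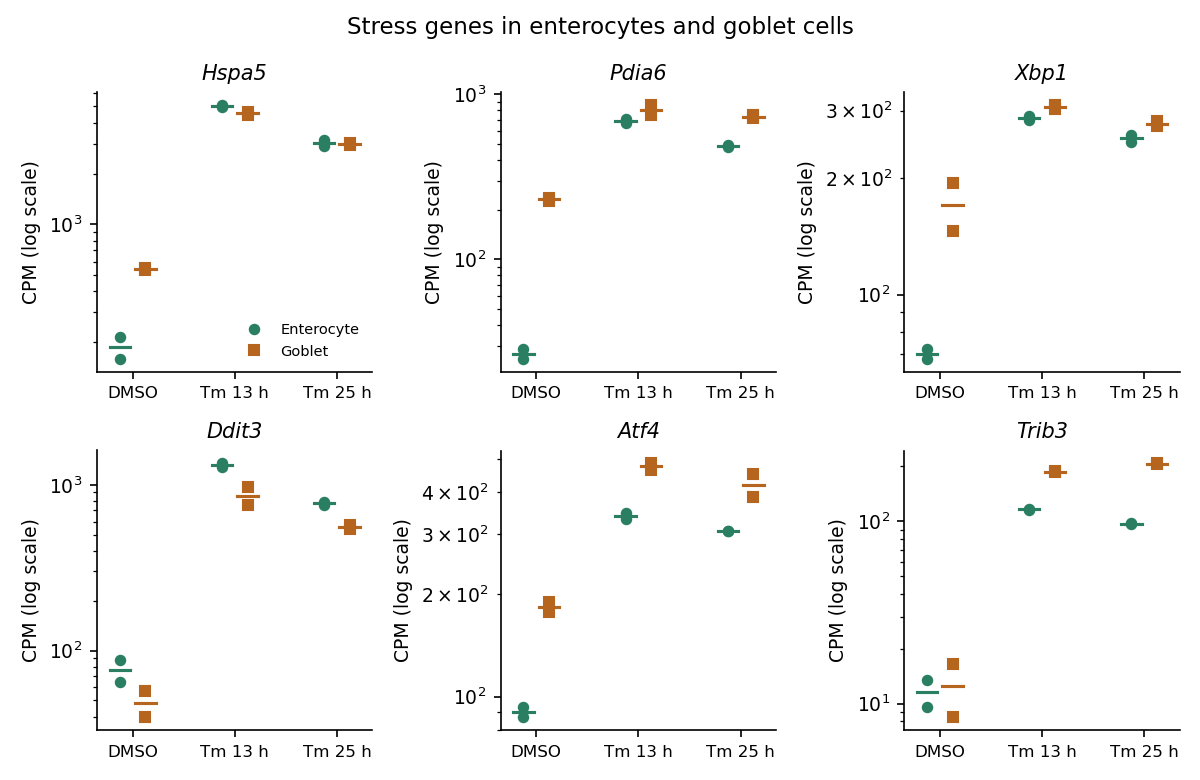
CPM on a log axis of Hspa5, Pdia6, Xbp1, Ddit3, Atf4 and Trib3 per library (points) with the mean of 2 libraries (bars), in enterocytes and goblet cells. Hspa5 in DMSO stands at 187 CPM in enterocytes and 544 in goblet cells.

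In enterocytes 20 of 21 chaperone genes rose at 13 h (median 2.24), all 17 PERK-ATF4 regulators (2.04) and all 18 genes of amino acid synthesis (2.42), while 18 of 20 cholesterol genes (-0.46) and 14 of 16 interferon-response genes (-0.81) fell. Camera gave adjusted p = 3e-16, 1.15e-10, 4.34e-12, 2.97e-07 and 3.66e-06 (adjusted p = 0.220, 0.220, 0.220, 0.277 and 0.266 with an estimated correlation). In goblet cells 18 of 20 chaperone genes rose (1.37), all 16 PERK-ATF4 regulators (2.21) and all 17 genes of amino acid synthesis (1.87), while all 20 cholesterol genes (-1.18) and 13 of 14 interferon-response genes (-1.98) fell. Camera gave adjusted p = 2.56e-15, 2.56e-15, 2.23e-15, 1.7e-14 and 7.88e-12 (adjusted p = 0.120, 0.120, 0.0785, 0.120 and 0.0785 with an estimated correlation). Adjusted over the list alone these numbers were the same, except for 19 chaperone genes in goblet cells. At 25 h ribosomal protein genes rose in 76 of 92 cases in enterocytes (0.80) and in 83 of 89 in goblet cells (1.49), also 76 and 83 adjusted over the list alone (camera, adjusted p = 7.21e-15 and 6.52e-34; adjusted p = 0.288 and 0.248 with an estimated correlation). Enterocyte markers fell in 17 of 18 cases within enterocytes at 25 h (-0.81), also 17 adjusted over the list alone (camera, adjusted p = 5.09e-08; adjusted p = 0.236 with an estimated correlation).

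The genes named next for goblet cells alone were chosen after their values were seen. Zg16 fell (-1.20 ± 0.15 at 13 h and -2.62 ± 0.15 at 25 h), Tff3 fell (-0.81 and -1.03), and Muc2 fell (-1.43 ± 0.12 and -0.80 ± 0.11), with a rise between 13 h and 25 h (0.63, adjusted p = 0.0026). Enterocytes counted among the goblet cells would lower such genes too, and a partial admixture at 25 h cannot be told apart from falls within goblet cells. Agr2 rose (0.61 ± 0.10 and 1.04 ± 0.10), and Clca1, which encodes a secreted protein of mucus, was at -0.20 at 25 h (adjusted p = 0.392). Of 13 goblet markers 2 rose and 9 fell at 13 h, and 2 rose and 10 fell at 25 h (2 and 9, and 2 and 10 adjusted over the list alone, camera adjusted p = 0.00142 and 0.00139; adjusted p = 0.387 and 0.364 with an estimated correlation). The serine synthesis genes Phgdh (4.36 ± 0.32) and Psat1 (3.42 ± 0.27) rose at 13 h in goblet cells, and the interferon-induced Ifit1 (-4.19 ± 0.21) and Isg15 (-2.92 ± 0.21) fell.

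The response differed between goblet cells and enterocytes for 503 of 10458 genes at 13 h, 738 at 25 h and 55 for the change between the times (edgeR interaction test, adjusted p below 0.05). Hspa5 rose less in goblet cells, with a difference of -1.75 ± 0.10 on the log2 scale at 13 h (adjusted p = 4.68e-16), from a DMSO level that was higher there. The same held for Xbp1 (-1.22 ± 0.13, adjusted p = 2.59e-08) and Atf4 (-0.58 ± 0.12, adjusted p = 0.00102). For Ddit3 the difference was -0.01 (adjusted p = 0.997). Without DMSO replicate 1 the 3 numbers of genes were 224, 373 and 31. The first was 313 without DMSO replicate 2 and 264 without 13 h replicate 1, and the second was 443, 450 and 479 without DMSO replicate 2, 25 h replicate 1 and 25 h replicate 2. The last was 24, 13, 34 and 27 without 13 h replicates 1 and 2 and 25 h replicates 1 and 2.

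In single enterocytes the share of UMIs from stress genes was higher in most cells. After thinning to 5000 UMIs, 94.6 ± 2.12% of enterocytes at 13 h and 98.3 ± 0.762% at 25 h (SD, n = 2) lay above the 95th percentile of DMSO enterocytes for the summed share of ER chaperone genes. Their median share was 0.26% of UMIs in DMSO, 1.91% at 13 h and 1.31% at 25 h. For PERK-ATF4 regulators 83.4 ± 0.675% and 76.8 ± 3.52% of enterocytes lay above that limit. For ribosomal protein genes 14.1 ± 2.08% and 41.2 ± 5.25% did, with median shares of 7.45%, 9.84% and 14.2% of UMIs. Of goblet cells 35.9 ± 2.27% and 83.7 ± 9.31% lay above the limit for ribosomal protein genes in DMSO goblet cells.

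**Figure D4:**
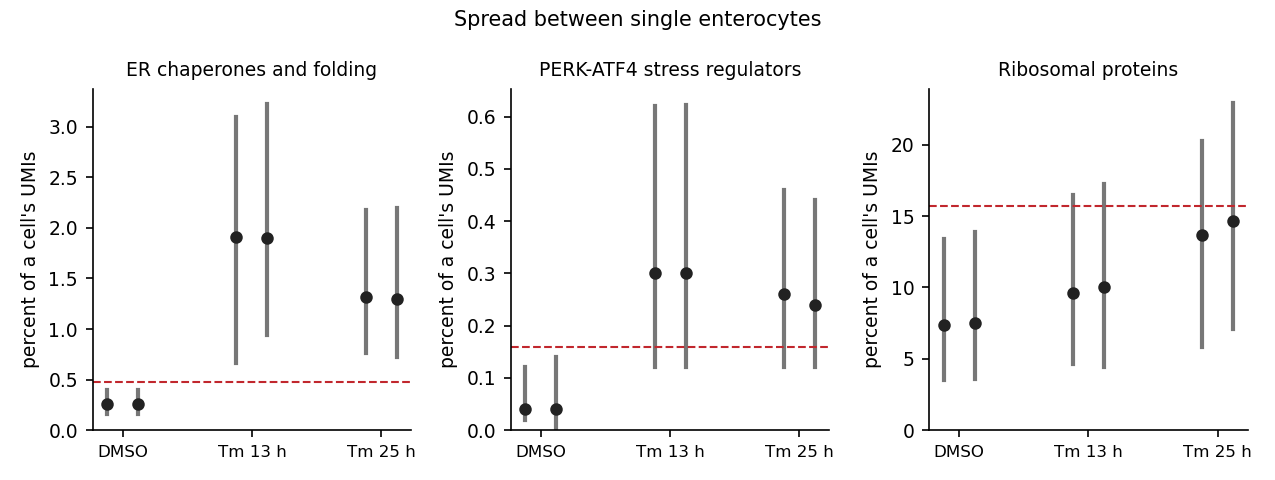
Share of UMIs from ER chaperone, PERK-ATF4 and ribosomal protein genes in single enterocytes thinned to 5000 UMIs. Points are medians of single libraries, lines run from the 10th to the 90th percentile of its cells, and the dashed line is the 95th percentile of DMSO, above which 94.6% of cells lay at 13 h for chaperones.

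Positions are given on GRCm38 for the stress genes of the comparisons, all annotated as protein coding. Hspa5 (ENSMUSG00000026864) lies on chromosome 2 from 34771970 to 34777547, Pdia6 (ENSMUSG00000020571) on chromosome 12 from 17266545 to 17284770, and Derl3 (ENSMUSG00000009092) on chromosome 10 from 75893413 to 75895941. Ddit3 (ENSMUSG00000025408) lies on chromosome 10 from 127290774 to 127296288, Atf4 (ENSMUSG00000042406) on chromosome 15 from 80255184 to 80257541, and Xbp1 (ENSMUSG00000020484) on chromosome 11 from 5520659 to 5525893. Dpagt1 (ENSMUSG00000032123) lies on chromosome 9 from 44326019 to 44333900, and Qrich1 (ENSMUSG00000006673) on chromosome 9 from 108516806 to 108560163.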

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

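The 3 tests of the goblet share were chosen after the result was seen, as was a first version of the test for enterocytes counted among goblet cells, and the limit for excluding these was changed after its result was seen. The other values are differences in response between goblet cells and enterocytes, each found by a test of the difference itself (goblet minus enterocyte, log2 scale). Genes were tested with the edgeR interaction test. Lists were tested with camera on the same difference, at the preset correlation of 0.01 unless an estimated correlation is named.

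The change differed between the classes for 503 genes at 13 h (155 above in goblet cells, 348 below), 738 at 25 h (267 above, 471 below) and 55 for the change between 13 h and 25 h (32 above, 23 below). Without DMSO replicate 1 these numbers were 224, 373 and 31. Without DMSO replicate 2 the first was 313 and the second 443, and without 13 h replicate 1 the first was 264 and the last 24. Without 25 h replicate 1 the second was 450 and the last 34, without 25 h replicate 2 they were 479 and 27, and without 13 h replicate 2 the last was 13. Hspa5 rose less in goblet cells at 13 h (-1.75 ± 0.10, adjusted p = 4.68e-16) and at 25 h (-1.62). Xbp1 did so as well (-1.22 and -1.19), and Atf4 (-0.58 at 13 h and -0.62 at 25 h). For Dpagt1 the difference was -1.18 at 13 h (adjusted p = 3.45e-04) and -0.43 at 25 h (adjusted p = 0.280).

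Among gene lists at 13 h, the median difference was -1.07 for ER chaperones (18 of 20 below, 1 above, adjusted p = 1.55e-15) and -0.53 for translocation genes (15 of 27 below, adjusted p = 1.61e-06). It was -0.75 for cholesterol genes (17 of 20 below, adjusted p = 1.74e-11) and 0.48 for ribosomal proteins (76 of 90 above, 1 below, adjusted p = 2.82e-29). Adjusted p = 0.336, 0.368, 0.336 and 0.336 with an estimated correlation. Goblet markers differed by a median of -1.03 (10 of 13 below, 1 above, adjusted p = 1.38e-04), and adjusted p = 0.395 with an estimated correlation. Interferon-response genes differed by a median of -1.74 (7 of 17 below, adjusted p = 4.11e-08), and adjusted p = 0.259 with an estimated correlation. In enterocytes Muc2 stood at 9.56 CPM in DMSO against 1498 CPM in goblet cells. Not all goblet markers were that low in enterocytes. By counts pooled over the DMSO libraries without TMM, Zg16 was at 200 CPM against 59806 in goblet cells, and Tff3 at 1631 against 95332.

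At 25 h the median difference was -0.93 for ER chaperones (15 of 20 below, 1 above, adjusted p = 3.49e-11), -0.67 for cholesterol genes (14 of 20 below, adjusted p = 1.85e-08) and 0.67 for ribosomal proteins (80 of 90 above, 1 below, adjusted p = 2.15e-38). Adjusted p = 0.421 in each case with an estimated correlation. Interferon-response genes differed by a median of -1.84 (10 of 17 below, adjusted p = 3.71e-08), and adjusted p = 0.257 with an estimated correlation. The median was -0.86 for small-intestinal genes (5 of 8 below, adjusted p = 0.0191), -0.97 for goblet markers (8 of 13 below, 1 above, adjusted p = 7.51e-04) and -0.67 for enterocyte markers (7 of 18 below, 2 above, adjusted p = 0.0359). Adjusted p = 0.498, 0.461 and 0.498 with an estimated correlation. The small-intestinal list shares genes with the enterocyte markers.

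Goblet cells were a larger share of cells at 25 h. A first test, on 48 goblet-enriched genes within the goblet class, found 3 higher (6.25%, 95% exact interval 1.31 to 17.2) and 32 lower with a median of -0.73, which decided nothing, since admixed enterocytes would lower them. It was replaced by 62 genes enriched in enterocytes, with an enrichment limit lowered after a stricter one left 1 gene: they stood in the goblet class at 25 h at a median of 18.0% of their enterocyte level (16.4% in DMSO, upper quartile 23.6%, or 26.1% and 22.2% in 25 h replicates 1 and 2). These genes were picked by a level at least 5-fold above goblet cells in the same DMSO libraries. The DMSO percent, and any change from it, is biased by that choice. To account for the whole rise, enterocytes would have to be 46.3% of the goblet class (at least 40.7% for any pair of libraries). Of the genes, 4 reached that level at 25 h, which argues against enterocytes as the whole cause, although a first, stricter limit of 23.1% for the upper quartile was missed. A part of the rise may come from enterocytes and cannot be told apart from goblet cells (median change 1.99 points from DMSO, quartiles -1.90 and 9.14). Nor can a loss of enterocytes be told apart from a gain of goblet cells, because the number of cells loaded is not given: goblet cells per library went from 107 to 92 (ratio 0.860) and enterocytes from 1041.5 to 436.5 (ratio 0.419). The preset enterocyte markers stood in the goblet class at 81.1% and 86.2% of their enterocyte level in DMSO and at 90.9% and 74.7% at 25 h. They are high there without tunicamycin too, so they cannot gauge such an admixture.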

How the results depend on the processing

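Of the alternatives for single named genes, 5674 kept direction and side of the threshold, 191 lost the call, 49 gained it and 2 reversed. For single lists in all cells the numbers were 849, 63 (50 of them from the estimated correlation), 33 and 0, and for class shares 85 and 5 lost. Alternatives for class shares other than the stricter cell filter and doublet removal, those for class differences and for the overlap of calls, the tuft class and unthinned cells were chosen after seeing the data. Where a sample is left out, the lone sample of its group is assumed to vary like the other groups. The planned clustering resolutions, component number and pooled fallback were not run, since the authors' classes were used. Depth limits the smaller classes, with 75 to 109 goblet cells and 12 to 27 cells of the class named tuft per library. The spread between cells moved by more than the spread between replicates without thinning in 3 of 6 values. The cause of the changes was not tested.

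With DESeq2 the number of genes lower at 13 h was 1855, and 515 rose and 696 fell from 13 h to 25 h. In enterocytes 1723 were higher at 13 h and 1922 at 25 h, and 538 rose and 737 fell from 13 h to 25 h. In goblet cells the numbers higher and lower were 425 and 372 at 13 h, 573 and 638 at 25 h, and 103 and 55 between the times. Genes called in opposite directions at 13 h and 25 h were 18 with DESeq2 and 24 with equal numbers of cells. With an estimated correlation 0 lists were called higher and 0 lower in each of the 3 comparisons. Fry called 13 lists lower at 13 h and 15 at 25 h. The enterocyte share at 25 h was -0.15 on the log2 scale with the stricter cell filter, and the goblet share 0.70, both against DMSO.

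With each sample left out in turn, the numbers from 13 h to 25 h ranged from 525 to 976 higher and 645 to 1058 lower, and in enterocytes from 766 to 996 higher. In goblet cells they ranged from 500 to 846 higher and 533 to 925 lower at 13 h, from 802 to 1255 higher at 25 h, and from 90 to 152 higher and 49 to 97 lower between the times. Genes that differ between classes ranged from 224 to 527, 373 to 706 and 13 to 52. Opposite calls ranged from 24 to 44, and the enterocyte share at 25 h from -0.16 to -0.12. Lrmp at 25 h against DMSO ranged from -0.46 without 25 h replicate 1 to 2.52 without 25 h replicate 2. Sct from 13 h to 25 h ranged from -0.64 without 25 h replicate 2 to 0.31 without 25 h replicate 1.

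With a replicate block, 2340 genes rose and 2664 fell at 13 h, 2728 and 2907 at 25 h, and 917 and 983 between the times, although the numbers do not pair the samples.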

Other observations

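The tests of tuft markers were chosen after the result was seen, as was the fit of the tuft class. Those of clock genes were written before their values were looked up, once Dbp and Per3 had been seen, but the allowance for error in the test of a clock shift was added after its result was seen.

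Mt1 and Mt2 encode metallothioneins, which bind zinc and copper. Mt2 in enterocytes was at -0.55 ± 0.10 at 13 h and -4.15 ± 0.16 at 25 h against DMSO (SE, n = 2 libraries per group). Mt1 in enterocytes was at -0.93 at 13 h and -2.91 at 25 h, and in goblet cells it rose at 13 h (0.56 ± 0.19, adjusted p = 0.038) and fell at 25 h (-1.01 ± 0.21). Reads of Mt1 and Mt2 may be shared in part, and the share was not analysed here. The EGF receptor ligand gene Areg rose in enterocytes (3.29 ± 0.08 at 13 h and 2.62 at 25 h) and in goblet cells (2.96 ± 0.17 and 3.07). From 13 h to 25 h it fell in enterocytes (-0.67). The chemokine gene Ccl20 rose in both classes at 13 h (2.24 in enterocytes, 1.85 in goblet cells) and at 25 h (1.49 and 0.88). These genes were chosen within classes after their values were seen. In the class named tuft Ddit3 at 13 h was at 4.64 ± 0.45, Herpud1 at 4.06 ± 0.34, Sdf2l1 at 3.78, Trib3 at 2.99, Hspa5 at 2.94 ± 0.25 and Pdia6 at 2.53, while the enteroendocrine hormone gene Sct fell (-3.65 ± 0.61, adjusted p = 0.014). Cells with at least 3 enteroendocrine markers, a list that includes Sct, were 9 of 45 in DMSO and 2 of 36 at 13 h. Cells with at least 3 goblet markers were 20 and 5, which 763 of 2057 enterocytes in DMSO also had. Cells with at least 3 enterocyte markers were 39 of 45 in DMSO and 11 of 36 at 13 h. These counts differ between the groups, but enterocyte markers also fell within enterocytes at 13 h (median -0.67). Whether the mix of cells in the class or the marker levels of its cells differ is not settled. The fold changes in this class are therefore not read as changes within tuft cells. In that class 38 genes rose and 9 fell at 13 h. The number that rose was 25 and 20 without DMSO replicates 1 and 2, and 85 and 71 without 25 h replicates 1 and 2. The number that fell was 30 without DMSO replicate 1, 16 and 32 without 13 h replicates 1 and 2, and 74 and 47 without 25 h replicates 1 and 2.

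Tuft markers were higher in the sums of all cells at 13 h. Their level in enterocytes and goblet cells was 0.934 times that in DMSO (1.87 and 4.03 CPM in DMSO, 2.82 and 2.69 at 13 h), or 0.684 and 1.47 times without DMSO replicates 1 and 2. These levels rest on 35 and 73 UMIs in DMSO and 37 and 38 at 13 h. Of all tuft marker UMIs, 87.2% and 92.9% at 13 h lay in the class named tuft, against 73.3% and 30.5% in DMSO. The 13 h shares argue against a rise outside the class as the source. Within the class, cells with at least 3 tuft markers made up 10 of 36 at 13 h and 2 of 45 in DMSO, a first test that only restates the rise and was replaced. Enterocyte markers in the class stood at 18.2% and 39.0% of their level in enterocytes in DMSO and at 14.0% and 16.8% at 13 h. That is a ratio of 0.538 (0.394 and 0.848 without DMSO replicates 1 and 2), against 0.966 in the goblet class. In the goblet class they stood at 81.1% and 86.2% in DMSO and at 82.3% and 79.3% at 13 h. All 199 DMSO goblet cells at equal depth also held at least 3 of them, so the list is no direct gauge of enterocyte content. Cells of the class with at least 3 enterocyte markers were 22 of 26 and 17 of 19 in the DMSO libraries, and 4 of 17 and 7 of 19 at 13 h. That share was lower in both 13 h libraries, but these markers also fell within enterocytes at 13 h (median log2 fold change -0.67). A different mix of cells inside the class may account for the rise of tuft markers, but the DMSO libraries differ too much in the ratio above to decide. A changed mix thus cannot be told apart from a rise within tuft cells, which was not tested.

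The clock genes Dbp and Per3 were lower at 13 h than in DMSO (-0.83 ± 0.06 and -0.86 ± 0.08) and higher at 25 h than at 13 h (1.28 and 0.91). In enterocytes alone they were at -0.79 and -0.83, or 96.0% of the fall in all cells, which argues against a changed mix of classes. For a shifted phase of the circadian clock, 6 further measured clock genes were predicted to be lower at 13 h. Of these 2 were lower (Nr1d1 -0.88, Tef -0.35) and rose by 25 h (0.69, 0.27). That is fewer than the bound of 3 set in advance, but not by more than the error, with Nr1d2 at -0.19 ± 0.10 and then rising (0.54). Of 4 genes of the opposite phase 2 were higher and then fell, as a shift would give (Arntl 0.40, then -1.04, and Cry1 0.29, then -0.78). The others did not pass at 13 h: Npas2 was at -0.02 (edgeR, adjusted p = 0.797), although it fell by 25 h (-0.62), and Clock at 0.09 (adjusted p = 0.275). Among the 6 genes predicted to be lower, Per1 (-0.13, adjusted p = 0.375) and Per2 (0.04, adjusted p = 0.777) did not pass at 13 h either, and Ciart rose (2.20 ± 0.16). A shift of the clock thus stays open, and so does a response of single clock genes to tunicamycin, which was not tested. Per the labels all sets were harvested on the same morning, so 13 h and 25 h are separate cultures rather than different hours of harvest. They differ in when tunicamycin was added, and the hour of addition cannot be told apart from the duration.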
